A study of Mus musculus with 10 samples.

How the data were processed

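Small RNA was sequenced from 10 mouse placentas (E13.5), 5 control and 5 ICSI-F2. Total RNA, a NEBNext small RNA library kit and single-end reads on a NovaSeq X Plus were used, per the labels' protocols. The genome build was mm39, per the submitters' processing notes. The aligner, the counter, the miRNA annotation and the treatment of reads that match several miRNAs are not given in the sources used here. The design text of the series speaks of another tissue and library type. The labels, the title and the values were followed. The labels do not say whether placentas came from the same litter or what their sex was. The p-values therefore measure only the spread between these samples, which may include litter.

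The values are RPM (reads scaled to the authors' total) of 847 mature miRNAs, per the file headers, deposited as 1 table for all 10 libraries. The columns sum to 426029 to 667948 RPM, so the authors' total is larger than the listed miRNA reads. Every value of a library was a whole multiple of what 1 read is worth (100% of values within 0.01 read), which gave back the reads. In 5 libraries the smallest value corresponds to 2 reads, so 1 read was taken as 0.5 of it. Values of 1 read were almost absent (7 of 8470). The libraries held 15060389 to 25317105 listed miRNA reads of totals of 33317388 to 53715430. At this depth 1 RPM stands for 33.3 to 53.7 reads, so counting error is small beside the spread between placentas. Reads are not molecules, since no molecular identifiers are mentioned.

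A test on counts had been planned. Because the table holds RPM, the stated fallback was used, limma (3.58.1, empirical Bayes with a mean-variance trend) on log2(RPM + 1). It took in the 600 miRNAs at 1 RPM or more in at least 5 libraries, with Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(RPM + 1) scale, which understates changes of low miRNAs. The groups, the tests, the rule for named miRNAs and 18 lists of miRNAs were fixed before the data were examined. The lists are genomic clusters, families and markers of other cell types that a placenta sample could hold. The 14 lists with 5 or more tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry (all in limma). The share of each list in the miRNA reads was compared with a two-sided exact permutation test over all arrangements of the 10 libraries, adjusted over the 18 lists. Arm balance was tested with limma on log2((5p reads + 0.5)/(3p reads + 0.5)) for hairpins with both arms above the filter.

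The rule named up to 15 higher and 15 lower miRNAs past the threshold, those with the smallest p up to 20, the 10 most abundant and up to 4 abundant members of each list. It gave 86 miRNAs, of which 0 passed. Others named in the text were chosen after their values were seen, among them miR-223-3p, miR-223-5p, miR-150-5p, miR-302b-3p, miR-125b-1-3p, miR-215-3p, miR-181a-5p, miR-221-3p, miR-483-5p and the hairpins. Copies that share sequence are uncertain as single miRNAs, such as the C2MC families, miR-199a-3p with miR-199b-3p and miR-486a with miR-486b.

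The tests were tried on simulated data with known answers for the comparison of ICSI-F2 with control (600 miRNAs). There limma recovered 43.3% of 1.5-fold, 86.6% of 2-fold and 97.0% of 4-fold changes and falsely called 2 of 400 unchanged miRNAs. edgeR recovered 59.7%, 92.5% and 98.5% with 1 false call. The changed miRNAs numbered 67, 67 and 66 of the 600. So many changes make the adjusted threshold easier to reach, so these percentages do not hold where few miRNAs change. For the arm balance (192 hairpins) 17 of 20 changes of 2-fold were recovered with 1 false call. The Dlk1-Dio3 list, shifted by -0.3 on the log2 scale, was recovered by camera, which also called 1 of 13 other lists. The simulated miRNAs varied independently of each other, whereas the estimated correlation of this list in the data was 0.847. The trial therefore does not cover camera at the preset correlation where members move together.

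Alternatives were edgeR (4.0.16) and DESeq2 (1.42.0) on the recovered reads, limma-voom, other scalings (TMM, RLE, listed miRNA totals, the 5 most abundant miRNAs left out), filters and pseudocounts (0.1 and 5). The number in the library names was used as a term, the libraries with 63 were tested alone, and each library was left out in turn. R was version 4.3.3 and figures were drawn with matplotlib. Replicate numbers only follow the order of the records and pair nothing. Gene neighbourhoods come from an annotation of GRCm38.p6, another build than the authors', so no coordinates are printed.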

Results

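Small RNA libraries were made from E13.5 placentas of C57BL/6 mice, 5 of them controls from wild-type pregnant females and 5 of them ICSI-F2. The ICSI-F2 placentas came from wild-type females mated with males born after intracytoplasmic sperm injection (ICSI, the injection of a single sperm into an egg). The comparison between these groups asks whether placental miRNAs differ in the generation fathered by ICSI-derived males. Reads recovered from the deposited RPM values numbered 15060389 to 25317105 per library over 847 listed miRNAs. The listed miRNAs took 50.1% ± 4.96 of the authors' total in controls and 53.3% ± 9.96 in ICSI-F2 placentas (SD, n = 5 each). That difference did not exceed the spread (two-sided exact permutation test, p = 0.532). None of the 20 pairs of libraries within a group agreed within counting noise. The smallest chi-square per degree of freedom was 113.2, which is set against counting error only. Each library was counted as a sample of its own, which this value does not show to be independent. In 3 pairs, among them control replicates 4 and 5, the names share a number and a letter. The labels do not say whether such a pair shares a litter.

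The placental profile was led by miR-21a-5p, a broadly expressed growth-associated miRNA, which took 21.8% of the miRNA reads on average. The 10 most abundant miRNAs held 55.3% of the reads. After miR-21a-5p they were let-7i-5p, miR-26a-5p, let-7f-5p, let-7g-5p, miR-148a-3p, miR-10b-5p, miR-182-5p, miR-30d-5p and miR-143-3p. Mean levels of miR-21a-5p were 96299 ± 10202 RPM in controls and 126960 ± 16128 RPM in ICSI-F2 placentas (SD, n = 5 each). Its log2 fold change of 0.40 ± 0.14 (SE) did not pass the adjustment (limma, adjusted p = 0.352). The other 9 had log2 fold changes between -0.36 for miR-148a-3p and 0.26 for miR-10b-5p, and none of them passed.

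Several miRNAs of white blood cells were among those with the smallest p, with higher means in ICSI-F2 placentas that did not reach the threshold over all miRNAs tested. miR-142a-3p, made in blood-forming cells, was at 64.1 ± 15.9 RPM in controls and 138 ± 36.4 RPM in ICSI-F2 placentas (SD, n = 5 each). Its partner arm miR-142a-5p was at 280.7 ± 77.9 RPM against 529.5 ± 79.0 RPM. miR-155-5p, induced in activated immune cells, was at 199 ± 55.0 RPM against 422 ± 125 RPM. The log2 fold changes were 1.09 ± 0.23, 0.94 ± 0.21 and 1.07 ± 0.24 (SE, limma, adjusted p = 0.0662 for each). For each of the 3, every ICSI-F2 placenta lay above every control, for miR-142a-5p by a narrow margin (403.0 against 402.9 RPM). miR-146a-5p, a brake on innate immune signalling, was at 722 ± 141 RPM against 1068 ± 133 RPM (log2 fold change 0.58 ± 0.18, adjusted p = 0.352). All 5 ICSI-F2 placentas lay above its control mean. The granulocyte miRNA miR-223-3p had a log2 fold change of 0.07 ± 0.20, and its other arm miR-223-5p one of -0.19 ± 0.19. For miR-150-5p, a miRNA of mature lymphocytes, it was 0.20 ± 0.21.

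**Figure D1:**
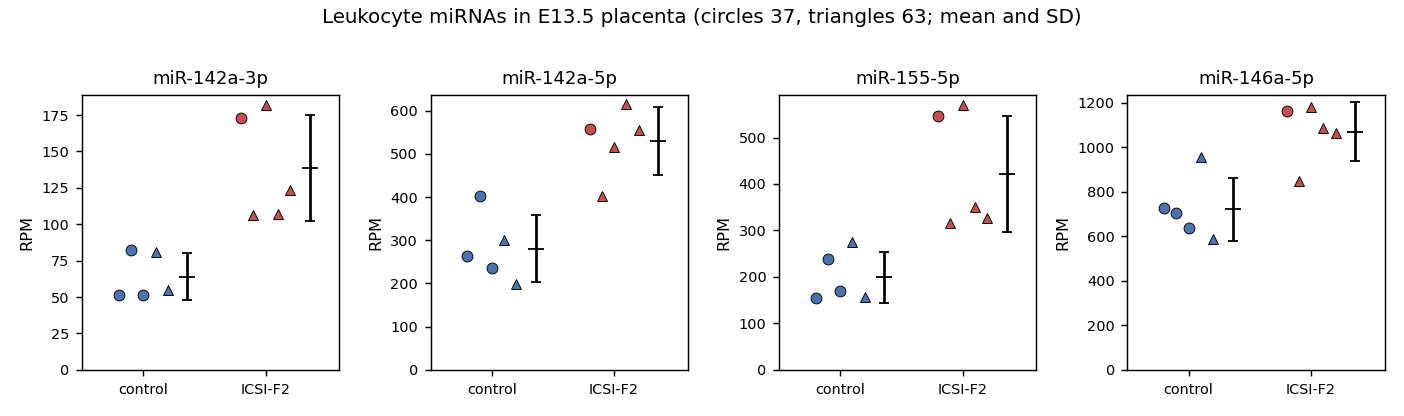
Levels in RPM of 4 leukocyte miRNAs (vertical axes, linear from 0) in each control and ICSI-F2 placenta; circles are libraries with 37 in their name, triangles those with 63, and the bars give the mean and SD of the 5 libraries. The points of the groups do not overlap for miR-142a-3p (means of 64.1 and 138 RPM), miR-142a-5p and miR-155-5p.

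Of the 7 tested members of the leukocyte list, 6 had higher means in ICSI-F2 placentas (5 when scaled to the listed miRNA reads). miR-142a-3p, miR-142a-5p, miR-155-5p and miR-146a-5p passed when adjusted over the list alone, and 0 passed over all 600 miRNAs tested. Relative to the other miRNAs the list passed as higher with a preset correlation (median log2 fold change 0.58, camera, adjusted p = 0.000181). It did not pass with an estimated correlation (adjusted p = 0.301). It passed with fry, which asks whether members move on balance in 1 direction (adjusted p = 0.0278). When the same libraries were regrouped, camera with the preset correlation called lists in 98 of the other splits, with a median of 6. Here and for the lists below, its p-value alone therefore says little about the groups. The mean log2 level of the leukocyte members differed by 0.54 over all libraries. The difference was 0.47 among libraries with the number 63 in their name and 0.71 among those with 37, of which only 1 is ICSI-F2. The list took 0.261% ± 0.0444 of the miRNA reads in controls and 0.423% ± 0.0892 in ICSI-F2 placentas, a ratio of 1.62. Every ICSI-F2 placenta lay above every control, although the closest libraries both rounded to 0.318%. The two-sided exact permutation p of this share was 0.00794, the smallest the design allows, and 0.0714 after adjustment over the 18 lists. Permuted within the name numbers it was 0.0167, again the smallest possible, and 0.0601 after adjustment over the 18 lists. The shares of the Dlk1-Dio3, other imprinted hosts, miR-200 and erythroid lists reached the same values there.

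Red blood cell miRNAs had 3 of 6 members higher and did not pass as a list (camera, adjusted p = 0.48). They passed with the number in the name as a term (adjusted p = 0.0252) and among libraries with 63 alone (adjusted p = 0.0193), both with the preset correlation. With an estimated correlation over all libraries the adjusted p was 0.781, and the direction was lower without control replicate 5 (adjusted p = 0.753) or control replicates 4 and 5 (adjusted p = 0.164). miR-451a, the main erythrocyte miRNA, was at 1101 ± 379 RPM against 1633 ± 422 RPM (log2 fold change 0.63 ± 0.28, limma, adjusted p = 0.488). For miR-486a-5p the log2 fold change was -0.13 ± 0.28.

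Across all 600 miRNAs tested, 0 passed the threshold (limma on log2(RPM + 1), lowest adjusted p = 0.0662). At an unadjusted p under 0.05 there were 55, of which 32 were higher and 23 lower in ICSI-F2 placentas. The balance turned on TMM-scaled RPM (69 higher and 80 lower) and with the number in the library names as a term (33 higher and 83 lower). For 8 miRNAs the groups did not overlap, where chance gives 0.79% of miRNAs. Outside the leukocyte list the smallest p belonged to miR-873a-5p, at 1.502 ± 0.581 RPM against 3.25 ± 0.624 RPM (log2 fold change 0.78 ± 0.17, adjusted p = 0.0662). miR-181b-5p followed at 515 ± 76.9 RPM against 759 ± 53.9 RPM (0.57 ± 0.17, adjusted p = 0.352). miR-147-3p, which inflammatory signals induce in macrophages, had a log2 fold change of 0.74 ± 0.24, and miR-147-5p one of 0.62 ± 0.21. Among those with lower means, miR-455-3p was at 16.2 ± 14.4 RPM against 5.22 ± 2.47 RPM (-1.23 ± 0.42, adjusted p = 0.352). miR-615-3p, which lies in the Hoxc cluster, was at 41.3 ± 22.2 RPM against 19.2 ± 7.24 RPM (-0.996 ± 0.334, adjusted p = 0.352). Without control replicate 2 the count was 3 and without control replicate 4 it was 2, all of them higher. On recovered reads edgeR called 0 of 714 miRNAs (186 at an unadjusted p under 0.05) and DESeq2 called 43, 15 higher and 28 lower.

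The library names carry an unexplained number, which is 37 for 3 controls and 1 ICSI-F2 placenta and 63 for 2 controls and 4 ICSI-F2 placentas. With that number as a term, limma called 10 miRNAs. Higher in ICSI-F2 placentas were miR-142a-3p, miR-142a-5p, miR-155-5p and miR-873a-5p. Lower were miR-302c-3p, miR-302b-3p, miR-125b-1-3p, miR-215-3p, miR-455-3p and miR-615-3p. With the same term edgeR on recovered reads, a fit chosen after the data were seen, called 49, 18 higher and 31 lower. Among the higher were 4 leukocyte miRNAs, with miR-142a-5p at a log2 fold change of 1.09 ± 0.21 (adjusted p = 0.0227). A further 4 came from the miR-322-503 cluster, with miR-450a-5p at 0.73 ± 0.13 (adjusted p = 0.0227). miR-451a (0.92 ± 0.19, adjusted p = 0.0235) and miR-21a-5p (0.55 ± 0.14, adjusted p = 0.0472) were also called higher. Among the lower were 19 members of the Dlk1-Dio3 cluster, such as miR-127-3p (-0.80 ± 0.16, adjusted p = 0.0227) and miR-379-5p (-0.55 ± 0.13, adjusted p = 0.0425). The lower calls also held 4 miRNAs of the miR-302 family, such as miR-302c-3p (-1.16 ± 0.24, adjusted p = 0.0235). They held 3 endoderm miRNAs, such as miR-215-5p (-1.62 ± 0.38, adjusted p = 0.0425). limma on TMM-scaled RPM with the number, also chosen after the data were seen, called 85, 29 higher and 56 lower. Of all these, 25 were called by both of the last fits and by DESeq2 without the number.

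In the Dlk1-Dio3 cluster, a run of miRNAs expressed from the maternal chromosome, 77 of 84 tested members had lower means in ICSI-F2 placentas (median log2 fold change -0.25). miR-127-3p was at 10979 ± 3466 RPM in controls and 7194 ± 3276 RPM in ICSI-F2 placentas (-0.67 ± 0.28, limma, adjusted p = 0.488). miR-379-5p was at 2763 ± 749 RPM against 2102 ± 788 RPM (-0.43 ± 0.25, adjusted p = 0.538). Relative to the other miRNAs the cluster passed as lower with the preset correlation (camera, adjusted p = 7.77e-10). It did not pass with an estimated one (adjusted p = 0.609). No member (0) passed over all miRNAs or when adjusted over the list alone. The cluster took 7.59% ± 1.97 of the miRNA reads in controls and 5.35% ± 1.08 in ICSI-F2 placentas (exact permutation p = 0.0714, adjusted p = 0.321). Control replicates 4 and 5, the only controls with 63 in their name, stood at 9.76% and 9.70%, while the other controls lay between 5.86% and 6.67%. The difference was -4.15 percentage points among libraries with 63 and -1.71 among those with 37 (exact permutation within the numbers, p = 0.0167, adjusted p = 0.0601). Without both of these controls the mean log2 level of the members differed by -0.05 in place of -0.26, which sets controls with 37 alone against ICSI-F2 placentas mostly with 63. The list passed there with the preset correlation (camera, adjusted p = 0.0104), while over all libraries it had not passed with an estimated one (adjusted p = 0.609). In the GRCm38.p6 annotation, 52 of 52 hairpin names of this list lie between Dlk1 and Dio3.

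The miRNA families of the large cluster in an intron of Sfmbt2 (C2MC, expressed in the placenta from the paternal chromosome) had higher means in 52 of 58 members, by small amounts. Their median log2 fold change was 0.16 (camera, adjusted p = 0.000184; adjusted p = 0.758 with an estimated correlation). The abundant miR-669c-5p was at 2642 ± 107 RPM against 2608 ± 784 RPM and miR-467a-5p at 2316 ± 164 RPM against 2531 ± 940 RPM. The share of the list was 1.88% ± 0.132 in controls and 1.89% ± 0.244 in ICSI-F2 placentas (exact permutation p = 0.937). These near-identical copies share reads, so single members are uncertain. Of their 36 hairpin names, 33 lie within Sfmbt2 in GRCm38.p6.

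The X-linked miR-322-503 cluster, tied to growth arrest, had higher means in 12 of 13 members. The median log2 fold change was 0.30 (camera, adjusted p = 0.00141; adjusted p = 0.609 with an estimated correlation). miR-450a-5p was at 3116 ± 282 RPM against 5066 ± 1888 RPM (0.63 ± 0.22) and miR-450b-5p had a log2 fold change of 0.58 ± 0.18. The share of the cluster was 4.90% ± 0.374 against 5.63% ± 1.11 (exact permutation p = 0.222). Without ICSI-F2 replicate 5 the difference was 0.332 percentage points in place of 0.731. Mean log2 levels of the C2MC and miR-322-503 members differed by 0.21 and 0.43 among libraries with 63. Among those with 37, of which 1 is ICSI-F2, they differed by -0.09 and -0.07, and the sign turned for both on TMM-scaled RPM.

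Epithelial miRNAs of the miR-200 family had lower means in 8 of 8 tested members (median log2 fold change -0.58). As a group they passed as lower with the preset correlation (camera, adjusted p = 0.000181). They did not pass with an estimated one (adjusted p = 0.609). miR-200c-3p was at 2343 ± 445 RPM against 1696 ± 828.6 RPM (-0.59 ± 0.29, limma, adjusted p = 0.488). miR-200b-3p was at 757 ± 528 RPM against 379 ± 158 RPM (-0.85 ± 0.40, adjusted p = 0.488). The family held 0.700% ± 0.167 of the miRNA reads in controls and 0.429% ± 0.131 in ICSI-F2 placentas, all 5 of which lay below all 5 controls. The exact permutation p was 0.00794 (adjusted p = 0.0714). The difference was -0.347 percentage points among libraries with 63 and -0.314 among those with 37. Control replicate 4 held the highest share, 0.996%. On the log2 scale the share ran opposite to the leukocyte share over the 10 libraries (Pearson's r = -0.77, Spearman's rho = -0.891, permutation p adjusted over 153 pairs of lists = 0.133 and 0.0493). The relation rested on ICSI-F2 replicates 1 and 3, without which r was -0.324 (permutation p = 0.491). Both shares separated the groups, and with each group centred on its mean r was -0.467. Among the 6 libraries with 63, r was -0.74 (exact permutation p = 0.075), and those with 37 were too few.

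**Figure D2:**
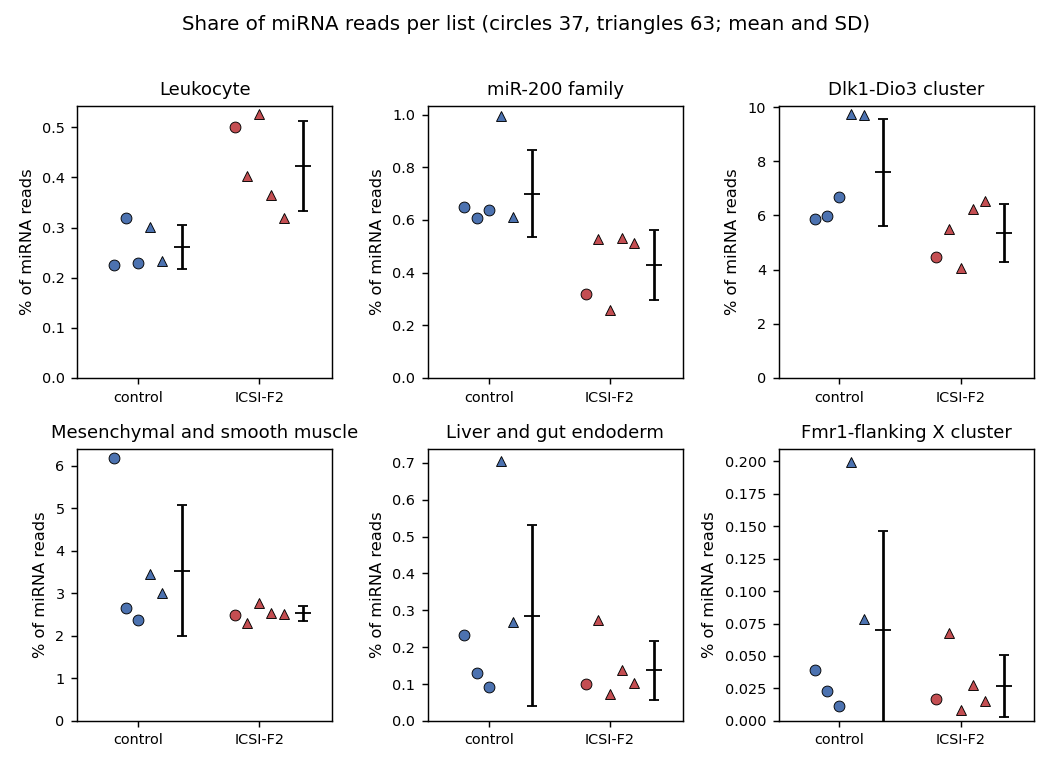
Percent of each library's miRNA reads (vertical axes, linear from 0) taken by 6 lists in control and ICSI-F2 placentas; circles are libraries with 37 in their name, triangles those with 63, and the bars give the mean and SD of the 5 libraries, with the lower bar of the Fmr1-flanking list in controls ending at 0. Leukocyte and miR-200 shares separate the groups, and single control libraries stand far above the rest for the mesenchymal (6.18%), endoderm (0.705%) and Fmr1-flanking (0.199%) lists.

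In a further 3 lists that passed as lower with the preset correlation, single control libraries stood far above the others. Endoderm miRNAs (of liver, gut and visceral endoderm) had lower means in 5 of 5 members (median log2 fold change -0.76). The list passed with the preset correlation (camera, adjusted p = 0.0105; adjusted p = 0.609 with an estimated correlation). miR-192-5p was at 979 ± 924 RPM against 452 ± 236 RPM and miR-215-5p at 202 ± 191 RPM against 77.4 ± 39.9 RPM. The Fmr1-flanking X cluster, known mostly from testis, had lower means in 18 of 19 members (median -0.68, camera, adjusted p = 0.00026; adjusted p = 0.609 with an estimated correlation). Its most abundant member miR-881-3p was at 138 ± 154.35 RPM against 49.2 ± 38.4 RPM. Both lists peaked in control replicate 4, where they took 0.705% and 0.199% of miRNA reads. Neither passed without ICSI-F2 replicate 5 (adjusted p = 0.141 for each) or without control replicates 1 and 4 (0.131 and 0.122). Within libraries with 63 their mean log2 levels differed by -1.49 and -1.79, and within those with 37 by -0.36 and -0.26.

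Mesenchymal and smooth muscle miRNAs had lower means in 10 of 10 members (median -0.35, camera, adjusted p = 0.00213; adjusted p = 0.609 with an estimated correlation). The smooth muscle miRNA miR-143-3p stood at 27000 RPM in control replicate 1 and between 8135 and 12580 RPM in the other controls. Without that library the list did not pass (adjusted p = 0.0631), nor among libraries with 63 alone (adjusted p = 0.116). The same library held 0.0782% of striated muscle miRNAs against at most 0.0152% in the others. The share of that list was 0.0241% ± 0.0305 in controls and 0.00634% ± 0.00183 in ICSI-F2 placentas, a difference that did not pass (exact permutation p = 0.0556, adjusted p = 0.321).

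**Figure D3:**
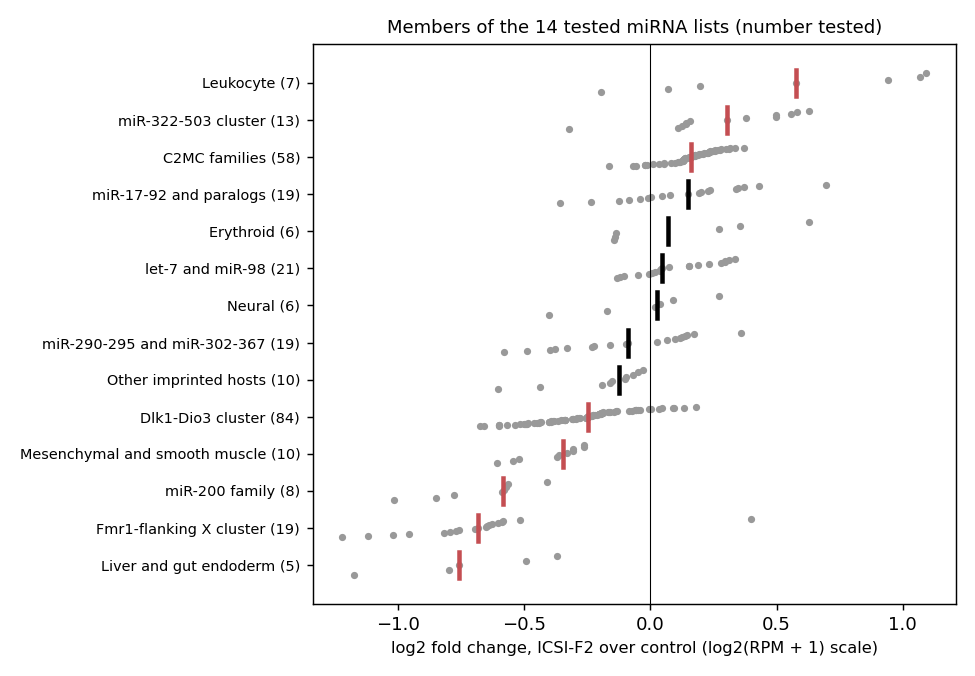
Log2 fold change of each member (grey points, horizontal axis, ICSI-F2 over control on the log2(RPM + 1) scale) of the 14 lists tested as groups, with the number of members tested in brackets; the vertical marks are medians, red where camera with a preset correlation passed and black where it did not. Medians run from -0.76 for the endoderm list to 0.58 for the leukocyte list, and 0 single members pass over all 600 miRNAs.

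The remaining lists did not pass as groups (camera). The miR-17-92 cluster and its paralogs, which drive proliferation, had 13 of 19 members higher (adjusted p = 0.0814). let-7 and miR-98 had 16 of 21 members higher (adjusted p = 0.0965), and 9 of 21 when scaled to the listed miRNA reads. The miR-290-295 and miR-302-367 clusters of the early embryo had 10 of 19 lower (adjusted p = 0.239), and passed as lower without control replicates 1 and 4 (adjusted p = 0.0378). miRNAs of the other imprinted hosts (Mest, H19, Igf2 and the Gnas region) had lower means in 10 of 10 members (median log2 fold change -0.12, adjusted p = 0.119). With the number in the name as a term, the lists of let-7 (adjusted p = 0.0212) and of these hosts (0.0372) passed. The let-7 list also passed without control replicate 1 (0.0273) or ICSI-F2 replicate 3 (0.0484), and the miR-17-92 list without ICSI-F2 replicate 1 (0.0416) or ICSI-F2 replicate 3 (0.0433). All these calls used the preset correlation; with an estimated one over all libraries the adjusted p was 0.758 for the let-7, imprinted-host and miR-17-92 lists and 0.781 for the miR-290-295 and miR-302-367 list. Neural miRNAs showed no common direction (median 0.03, or -0.05 when scaled to the listed miRNA reads, and mean -0.03, adjusted p = 0.98). A few lists were too short to test as groups. Of miR-34 and miR-449, 2 of 3 members were higher. The endothelial miR-126a-3p had a log2 fold change of 0.15 ± 0.16 and miR-126a-5p one of 0.34 ± 0.24. miR-210-3p, which hypoxia induces, had one of -0.14 ± 0.22. None of the 18 shares passed the adjustment, the smallest adjusted p being 0.0714 (exact permutation).

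The balance between the arms of a hairpin, a measure of processing that does not depend on scaling, differed for 0 of 192 hairpins (limma on the log2 ratio of 5p to 3p reads, lowest adjusted p = 0.0758). At an unadjusted p under 0.05 there were 35 hairpins, 21 toward the 5p arm and 14 toward the 3p arm in ICSI-F2 placentas. The smallest p belonged to miR-106b, whose log2 ratio was -1.82 in controls and -1.12 in ICSI-F2 placentas (difference 0.70 ± 0.15, SE). For miR-193a the ratios were 2.11 and 1.63 (difference -0.48 ± 0.11, adjusted p = 0.0811). Without ICSI-F2 replicate 2 the count was 2, miR-106b and miR-342.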

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

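All tests in this part were chosen after the results were seen, except the fixed rule for a library far from the others of its group. Of 210 groups of 5 values (shares and named miRNAs), 21 held such a library, where chance gives about 1 in 20. Control replicate 4 accounted for 10 of them and control replicate 1 for 5. Control replicate 4 stood above the other controls for the miR-200 family (0.996% of miRNA reads against 0.606% to 0.651%), miR-200a-3p (631 RPM) and miR-429-3p (237 RPM). It did so too for the endoderm list (0.705% against 0.0917% to 0.269%), miR-192-5p (2560 RPM), miR-194-5p (761 RPM) and miR-215-5p (536 RPM). The same library stood out for miR-741-3p (132 RPM) and miR-470-5p (95.5 RPM) of the Fmr1-flanking cluster and for miR-455-3p (41.0 RPM). Control replicate 1 stood above the other controls for mesenchymal and smooth muscle miRNAs (6.18% against 2.37% to 3.44%) and miR-143-3p (27000 RPM). It also held more striated muscle miRNAs (0.0782% against 0.00663% to 0.0152%), miR-1a-3p (396 RPM) and miR-133a-3p (22.9 RPM), while miR-206-3p, found in skeletal muscle, was at 11.7 RPM there. Control replicate 5 stood out for neural miRNAs (0.0603%), miR-9-5p (117 RPM) and miR-206-3p (28.7 RPM). Control replicate 3 stood out for miR-293-5p (1830 RPM). ICSI-F2 replicate 2 lay below the other ICSI-F2 placentas for miR-147-3p (139 RPM) and miR-21a-5p (99700 RPM).

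Endoderm and Fmr1-flanking X miRNAs moved together from placenta to placenta. On the log2 scale their shares had a Pearson's r of 0.985 and a Spearman's rho of 0.976 over 10 libraries (permutation p = 1e-05, the smallest that 100000 resamples give, and 5e-05; adjusted over 153 pairs of lists, p = 0.00153 and 0.00765). Control replicate 4 alone does not make the relation, since r was 0.973 (permutation p = 5e-05) without it and ICSI-F2 replicate 2, the libraries farthest from the median endoderm share. Among the 6 libraries with 63 r was 0.989 (exact permutation p = 0.00278), and the 4 with 37 were too few. Of the tested endoderm miRNAs, miR-192, miR-194 and miR-215 lie in shared clusters and are not independent. No biological explanation was tested for this relation, and it stays open which cells carry the X-linked cluster.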

How the results depend on the processing

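Alternatives marked as added, and all runs that leave out 2 controls, were chosen after seeing the data. The count of differing miRNAs was 0 with limma on log2(RPM + 1). It was also 0 with limma-voom, RLE or total scaling in edgeR, other filters, the added pseudocounts and added TMM scaling. It was 43 with DESeq2, 10 with the number in the name as a term and 29 among libraries with 63 only (1 higher and 28 lower, 2 controls against 4 ICSI-F2). It was 0 in limma-voom with number and letter of the name as correlated samples (consensus correlation 0.193, lowest adjusted p = 0.139). With the number as a term it was 49 in edgeR and 85 on TMM-scaled RPM (both added); the cause was not tested. Leaving out each library in turn gave 0 to 3. Lists called numbered 8 with the preset correlation, 0 with an estimated one and 1 with fry, and 6 to 11 under the other settings. The Fmr1-flanking list turned to a higher mean without control replicates 4 and 5 (adjusted p = 0.8649). The endoderm list did not pass on TMM-scaled RPM (0.0742) or without control replicates 4 and 5 (0.207). Without control replicates 1 and 4 the mesenchymal list did not pass (0.27), whereas the leukocyte, Dlk1-Dio3 and miR-200 lists did (6.78e-05, 4.46e-09 and 0.00463). Shares passing numbered 0 under each alternative, and arm calls 0 to 2 with a library left out and 0 otherwise. Of 238 list values, 204 stayed on their side of the threshold, 24 lost the call and 9 gained it. Of 2391 values of named miRNAs, 86 gained a call and 97 uncalled values changed sign. A call could not be lost, since 0 named miRNAs were called in the main fit. No paired analysis was possible because replicate numbers carry no pairing. Of libraries sharing number and letter there were 3 pairs, with correlations of their deviations from -0.57 to 0.68. Depth limits little here, since 1 RPM stands for at least 33.3 reads.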

Other observations

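All tests in this part were chosen after the results were seen, except the counts over other splits for the fits planned beforehand. Outside the lists, some miR-181 miRNAs had higher means in ICSI-F2 placentas, whereas miR-181a-2-3p and miR-181c-3p had log2 fold changes of -0.17 and -0.09. miR-181a-1-3p was at 56.9 ± 5.24 RPM in controls and 84.0 ± 13.4 RPM in ICSI-F2 placentas (SD, n = 5 each; limma, log2 fold change 0.54, adjusted p = 0.352). Like miR-181b-5p it was higher in every ICSI-F2 placenta than in every control. With the number in the name as a term edgeR called both (0.69 ± 0.18 and 0.66 ± 0.17, SE, adjusted p = 0.0472). The same fit called miR-181a-5p (0.56 ± 0.15, adjusted p = 0.0472) and miR-221-3p (0.62 ± 0.14, adjusted p = 0.0414) higher. It called miR-125b-1-3p (-1.01 ± 0.17) and miR-483-5p, which lies in Igf2, lower (-0.63 ± 0.12, adjusted p = 0.0227 for both). Of 153 pairs of list shares, 5 passed the adjustment on r or rho (log2 scale, permutation tests). Besides endoderm with Fmr1-flanking and miR-200 with leukocyte, C2MC went with miR-17-92 and its paralogs (r = 0.916, rho = 0.903, adjusted p = 0.00459 and 0.0398). The r was 0.823 without ICSI-F2 replicates 3 and 5, the libraries farthest from the median, and 0.952 among the 6 libraries with 63. Dlk1-Dio3 went with the other imprinted hosts (r = 0.866, rho = 0.915, adjusted p = 0.0413 and 0.0398), with r = 0.777 without control replicates 4 and 5 and 0.939 among libraries with 63. C2MC with miR-322-503 passed on r only (r = 0.871, rho = 0.806, adjusted p = 0.0321 and 0.19), with r = 0.781 without ICSI-F2 replicates 3 and 5 and 0.874 among libraries with 63. The 4 libraries with 37 were too few to test.

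Holding the number in the names fixed did not shrink the higher leukocyte score of ICSI-F2 placentas. The mean of the within-number differences was 0.589 on the log2 scale beside 0.536 over all libraries. Its exact permutation p of 0.0167 is the smallest that the 60 regroupings allow. With 2 controls with 63 and 1 ICSI-F2 placenta with 37, this does not exclude the number as a cause. The authors' scaling does not account for the higher score, the difference being 0.522 on TMM-scaled RPM (exact permutation p = 0.0238). The members did not rise alike, since the SD of their log2 fold changes, 0.521, exceeded that of most regroupings (exact permutation p = 0.0159). This speaks against more white cells of every kind alike only if white cells are the sole source of each member. That was not tested. More blood of every kind cannot be told apart, because the leukocyte difference exceeded the erythroid one by 0.396 with a wide spread (exact permutation p = 0.19). The erythroid share of miRNA reads was also higher in ICSI-F2 placentas, by 0.157 percentage points within 63 and 0.114 within 37. Its exact permutation p was 0.0167 within the numbers (adjusted p = 0.0601) and 0.405 over all libraries. It stays open, as untested hypotheses, whether some immune cell types are more frequent in ICSI-F2 placentas, make more of these miRNAs per cell, or differ through litter, sex or dissection.

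For the lower Dlk1-Dio3 miRNAs, control replicates 4 and 5 cannot be told apart from the groups as the cause. Without them the score difference was -0.0515 (exact permutation p = 0.857) beside -0.264 with them, but this leaves only controls with 37, and within 37 it was -0.362 with 1 ICSI-F2 placenta. Holding the number in the name fixed did not shrink the difference in share. Its mean within the numbers was -2.93 percentage points (exact permutation p = 0.0167, the smallest possible) beside -2.24 over all libraries. The mean log2 level on the RPM scale did not pass within the numbers (-0.434, exact permutation p = 0.0667). With 2 controls with 63 and 1 ICSI-F2 placenta with 37, this does not exclude the number as a cause. TMM scaling did not shrink the score difference, which was -0.281 over all libraries beside -0.264 on RPM. On TMM-scaled RPM it did not pass over all libraries (exact permutation p = 0.0714). Within the numbers it was -0.371 (exact permutation p = 0.0167, the smallest possible). The size of the difference thus did not rest on the authors' scaling, while the tests disagree on whether it exceeds the spread. A difference between the groups, or something particular to control replicates 4 and 5 such as a shared litter, may each underlie the lower values, and 2 libraries cannot separate them.

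Chance was weighed by regrouping the same libraries. For miRNAs at an unadjusted p under 0.05, 20 of 100 splits gave as many as the real 55, the highest of the others being 281. That split set control replicates 1, 3 and 4 with ICSI-F2 replicates 4 and 5 apart from the rest, and 0 miRNAs passed the adjustment in it. Listed miRNAs took 49.4% to 66.8% of the authors' total on that side and 42.6% to 49.6% on the other, with a slight overlap. On RPM the mean log2 levels of C2MC members were 4.48 to 5.12 on that side and 4.27 to 4.43 on the other. On TMM-scaled RPM they overlapped (4.39 to 4.73 and 4.42 to 4.62). The miR-17-92 list also separated the sides on RPM (5.41 to 5.99 against 5.31 to 5.39) and overlapped on TMM-scaled RPM, while the miR-200 list overlapped on both. The RPM scaling may thus make part of this split, which was not fitted on another scaling. For lists, 22 of 100 splits gave as many as 8 (highest other 12), so chance cannot be excluded for either count. With the preset correlation camera called lists in 98 of the other splits, with a median of 6, so its p-values alone say little about the groups. For DESeq2, 2 of 100 splits gave as many as 43 (highest other 45), and 19 of the other splits held calls. For arm balance 1 of 100, the real one, gave as many as 35 hairpins at an unadjusted p under 0.05 (highest other 29). Few regroupings reached these counts of DESeq2 and arm balance. They did not hold the number in the names fixed, so chance within the number was not weighed for them. The fits with the number as a term were set against the 60 regroupings within the number. For limma 3 of 60 gave as many as 10 (highest other 56), which does not exclude chance. For edgeR (49 calls) and for TMM-scaled RPM (85 calls) 1 of 60, the real one, gave as many, and the highest other was 0. That is the smallest share the 60 regroupings allow. Both fits were chosen after the data were seen, and limma with the same term did not exclude chance, so chance stays open for them.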
